A study of Mus musculus with 5 samples.

How the data were processed

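Total RNA from ES-D3 cells, a mouse embryonic stem cell line, was measured in 5 libraries. Per the labels' protocols, the cells grew on an irradiated feeder layer with leukemia inhibitory factor, received a lentiviral short hairpin and were selected with puromycin, and feeder cells were depleted by replating for 30 minutes before extraction. Libraries were read on the Helicos platform, which sequences single molecules without amplification. The 5 libraries were grouped by the hairpin target in the labels: 1 with a hairpin against GFP, which served as the control, 2 with different hairpins against Trim28 and 2 with different hairpins against Wtx. Wtx is listed in the gene table under the older symbol Fam123b, and its current symbol is Amer1. The shTrim28 libraries carried hairpins 2065 (replicate 1) and 2856 (replicate 2), and those labelled shWtx carried hairpins 2460 (replicate 1) and 2461 (replicate 2). The libraries of a target carried different hairpins and so came from separate infections, with 1 library per hairpin. The p-values therefore measure the spread between hairpins, part of which may be technical, and the labels do not say that the cultures were otherwise separate. The hairpins against Wtx share 20 of 21 bases, and the spread of that pair also enters the tests of shTrim28.

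The authors deposited 2 tables of estimated counts without scaling between libraries. Reads were aligned to RefSeq for the gene table and to Repbase, a collection of repeat sequences, for the repeat table, per the labels, and mm9 was the build per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. In the table of genes as deposited, a single read was worth between 1.02 and 1.07 estimated counts, depending on the library, and some rows held fractions. In the deposited repeat table every estimated count above 0 and below 100 was a number with 2 decimals divided by 34 (tolerance 0.0003), as for aligned bases shared between elements. How the strand was used in counting is not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical copies, may have been split or merged. A deposited list of repeat classes and families was used to group the repeats.

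The gene table had 28642 rows, of which 19486 carried a gene symbol and 9156 a UCSC identifier with no symbol. The latter were kept in the tests and not named. The repeat table had 1221 rows. The totals of the gene table were 586408 estimated counts in the control, 280614 and 1901563 in shTrim28 replicates 1 and 2, and 763130 and 377794 in the libraries labelled shWtx replicates 1 and 2. Intervals for single libraries are exact 95% Poisson intervals and cover counting error only.

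Estimated counts were rounded to whole numbers. Rows were kept by the edgeR function filterByExpr with the 3 groups, which left 10878 gene rows and 900 repeat rows. The main test was edgeR's quasi-likelihood test with TMM scaling of the gene table on all 5 libraries, without covariates. Repeat rows were tested on their own and scaled by the effective library sizes of the gene table. The control was a single library, so the spread came from the pairs of hairpins (2 residual degrees of freedom, moderated across rows) and the control was assumed to vary like them. The biological coefficient of variation was 0.168 for genes and 0.262 for repeats. P-values were adjusted by the Benjamini-Hochberg method within each table and comparison, with a threshold of 0.05. Every adjusted p in the text comes from these edgeR or limma fits, and those tests are two-sided. Permutation tests and counts of random lists were taken in 1 direction, and the chi-square test of Cochran's Q in its upper tail. Standard errors of log2 fold changes were taken as the size of the change divided by the square root of the F statistic and are approximate. Levels are given as CPM, counts scaled to the effective library sizes of the gene table, except for chemoreceptor genes as a whole, which were divided by the library's gene total. Log2 fold changes compare the first group named with the second. For rows with 0 counts in 1 of the groups, the fold is given as a lower bound against a floor of 3 counts over that group, and for rows with 1 to 3 counts as a ratio with its exact 95% counting interval.

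The 3 comparisons were shTrim28 against the control, the libraries labelled shWtx against the control, and shTrim28 against the libraries labelled shWtx, each for genes and for repeats. Tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined. Named genes were Trim28 and Fam123b, Pou5f1, Nanog and Sox2, and the 10 symbols with the largest log2 fold change in each direction among those past the threshold with both libraries on the same side of the control. For shTrim28 against the libraries labelled shWtx it was 5 in each direction, and for repeats 8, filled to 5 by the lowest p where fewer passed. For each list spoken of, up to 4 members with the lowest p were named, and up to 3 for a repeat group. Other genes are said to have been chosen after their values were seen.

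The 24 gene lists covered pluripotency, primed epiblast, 2-cell-like cells, imprinted genes, the Trim28 silencing machinery, KRAB zinc finger proteins, germline genes, Wnt targets, the Wnt degradation complex, Nrf2 targets, mesendoderm, endoderm, neuroectoderm, trophoblast, fibroblasts as markers of the feeder layer, p53 targets, interferon response, cell cycle, glycolysis, unfolded protein stress, cholesterol synthesis, replication histones, ribosomal proteins and mitochondrial oxidative phosphorylation. They were tested with camera from limma with a preset correlation of 0.01, which compares a list with all other tested genes. Camera with an estimated correlation and fry were the alternatives. The estimated correlation rests on the 2 residual degrees of freedom, and no list passed with it in any comparison. Pluripotency genes, with 19 of 34 lower in shTrim28, and germline genes, with 1 of 8, had the same camera value (adjusted p = 0.353). A list with 19 of 34 members past the threshold thus missed it as a list, so a miss does not show a list to be unchanged. The 12 repeat groups, fixed by element name, were tested in the same way.

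Alternatives fixed before the data were examined were DESeq2 size factors, quantile normalization with limma-trend, the DESeq2 Wald test, no filter, a filter at a mean count of 20, a fit of only the 2 groups compared, leaving out each hairpin library in turn, and scaling repeats to their own total or median. The 5 further ones were chosen after seeing the data: repeats scaled to DNA transposons, gene rows with a transcript length only, counts after subtraction of a background in proportion to transcript length, that subtraction in transcripts with under 1% of repeated sequence, and counts divided by the worth of 1 read. The background was the reads per kilobase of 1349 chemoreceptor genes (olfactory, vomeronasal, trace amine and bitter taste receptors). Transcript lengths were found for 19171 of the 19486 symbols, from a GENCODE annotation of GRCm38. That annotation was used for lengths, chromosomes, repeated sequence and hairpin sites, and no coordinates of mm9 were used. Repeated sequence was the percent of a transcript's 24-base words found in at least 10 genes.

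The test was checked on simulated counts with the libraries' own depths, with 200 changed rows. At 2-fold it recovered 4% of changed genes for shTrim28 and 9% for the libraries labelled shWtx against the control, and 13% between the targets. At 4-fold it recovered 52%, 55% and 65%. For repeats the figures were 7%, 12% and 35% at 2-fold and 56%, 63% and 95% at 4-fold. In this simulation changes of 2-fold were therefore mostly missed. More than 200 genes were called in each comparison, which loosens the Benjamini-Hochberg cutoff, so recovery in the data may differ. In the libraries labelled shWtx, 71 of 77 ribosomal protein genes passed at a median log2 fold change of −0.94. The hairpin libraries of a target differed by more than counting noise, with a chi-square per degree of freedom of 2.61 over 10164 genes for shTrim28 and 1.72 over 8314 for the libraries labelled shWtx. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.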

Results

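RNA of mouse ES-D3 embryonic stem cells was counted by single-molecule sequencing in 5 libraries, 1 with a control hairpin against GFP, 2 with hairpins against Trim28 and 2 with hairpins against Wtx. Trim28 is a corepressor recruited by KRAB zinc finger proteins, and Wtx (Amer1, listed as Fam123b) is a component of the Wnt degradation complex. Gene totals ranged from 280614 to 1901563 estimated counts per library. Counts in chemoreceptor genes, which encode receptors of smell, pheromones and taste, differed between the libraries. They stood at 334 CPM in the control, 2310 and 1515 in shTrim28 replicates 1 and 2, and 4448 and 3827 in the libraries labelled shWtx. Repeat reads outside ribosomal RNA followed the same order. There were 0.419 of them per gene read in the control, and 1.77 and 1.27 times that ratio in shTrim28 and 2.73 and 2.43 times in the libraries labelled shWtx.

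The hairpin targets were located on GRCm38. The hairpin of shTrim28 replicate 1 (CCACCAGTCTTCAAGGTCTTT) matched coding sequence in exon 12 of 17 of Trim28, on chromosome 7 from 13029440 to 13029460. That of replicate 2 (CCGCATGTTCAAACAGTTCAA) matched coding sequence in exon 16 of the same gene, from 13030559 to 13030579. The hairpin of the library labelled shWtx replicate 1 (GCCAGACATGCAAGAAGCAAA) matched coding sequence in exon 2 of 2 of Amer1 on the minus strand of chromosome X, from 95426292 to 95426312. That of replicate 2 (CCAGACATGCAAGAAGCAAAT) matched from 95426291 to 95426311 and shared 20 of its 21 bases with the other, so both hairpins against Wtx cover 1 site.

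Trim28 was lower in both shTrim28 libraries, and no lower level of Fam123b was detected in the libraries labelled shWtx. Trim28 stood at 783 normalised CPM in the control (95% interval 711 to 860), at 65.3 (38.7 to 103) and 48.3 (38.6 to 59.6) in shTrim28, and at 400 (355 to 448) and 397 (334 to 467) in the libraries labelled shWtx. The log2 fold change was −3.88 (SE 0.29, adjusted p = 2.78e-09) in shTrim28 and −0.98 (SE 0.26, adjusted p = 0.0108) in the libraries labelled shWtx. In the latter, all genes with a mean of 100 to 400 CPM had a median of −0.42, and those over 400 CPM −0.69. Fam123b was counted 8 times in the control, which gave 14.3 CPM (6.19 to 28.23). It stood at 18.1 (5.89 to 42.3) and 30.3 (22.8 to 39.5) in shTrim28, and at 26.3 (15.8 to 41.02) and 16.5 (6.06 to 36.0) in the libraries labelled shWtx. Its log2 fold change in the libraries labelled shWtx was 0.65 (SE 0.63, adjusted p = 0.508). On unrounded counts, subtraction of the chemoreceptor level in proportion to transcript length took Fam123b from 15.22 to 14.59 in the control, and from 25.7 and 16.71 to 17.3 and 9.57 in the libraries labelled shWtx (log2 fold change 0.15, adjusted p = 0.923), so these few counts neither show nor exclude a knockdown. The libraries with hairpins against Wtx are called the libraries labelled shWtx throughout.

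**Figure D1:**
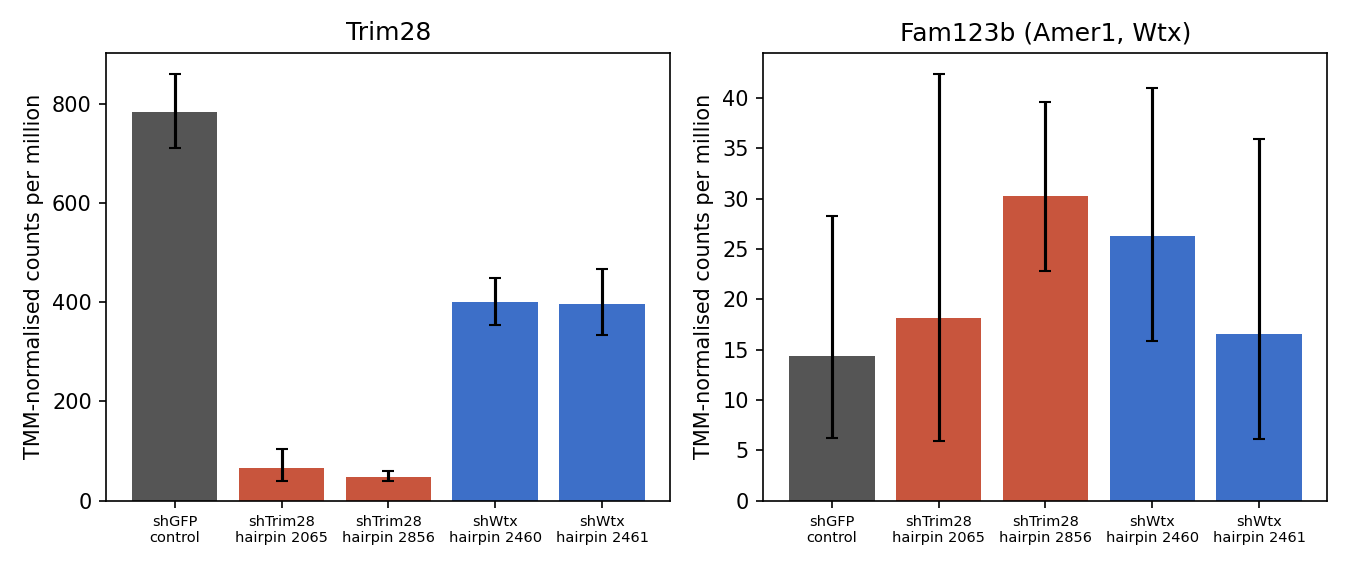
Normalised CPM of Trim28 and Fam123b (Wtx) in each of the 5 libraries, with exact 95% Poisson intervals as error bars. Trim28 is at 783 in the control and at 65.3 and 48.3 in the shTrim28 libraries, while the intervals of Fam123b overlap between the control and every other library.

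The first comparison asked which genes differed after knockdown of Trim28. Of the genes of the pluripotent state 19 of 34 fell, and of those of fibroblasts 14 of 38 rose, in shTrim28 relative to the control, and as lists both had adjusted p = 0.353 with an estimated correlation. Zfp42 (Rex1), a marker of naive embryonic stem cells, fell from 729 CPM in the control to 98.0 ± 22.03 (SD, n = 2), and Pou5f1 (Oct4), a core pluripotency factor, fell from 856 to 255 ± 61.0. The largest fall was that of Nr0b1 (Dax1), an orphan nuclear receptor of embryonic stem cells, from 77.0 to 3.31 ± 0.61, a log2 fold change of −4.64 (SE 0.57, adjusted p = 4.12e-06). Of 10878 genes tested, 710 passed the threshold, 464 higher and 246 lower. With DESeq2 size factors, which moved the median log2 fold change of all genes from 0.16 to 0.06, 390 were higher and 336 lower. Among genes with a transcript length, the majority turned: 321 were higher and 368 lower, 263 and 276 with the background subtracted, and 175 and 212 without repeated sequence as well.

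Of 34 pluripotency genes tested, 19 fell and 0 rose, and 23 fell when adjusted over the list alone. Their median log2 fold change was −1.26, below that of the other genes by camera (adjusted p = 2.13e-30; adjusted p = 0.353 with an estimated correlation). Besides Zfp42 (log2 fold change −2.98, adjusted p = 1.08e-07) and Nr0b1, the members with the lowest p were Utf1 (−2.61, adjusted p = 4.12e-06) and Dppa5a (−1.93, adjusted p = 1.09e-05). Pou5f1 fell by 1.80 on the log2 scale (SE 0.27, adjusted p = 5.48e-05), Sox2 by 1.31 (SE 0.30, adjusted p = 0.00763) and Nanog by 1.13 (SE 0.30, adjusted p = 0.0226). Of 13 genes of the primed epiblast, 1 rose and 3 fell. Those that fell were the DNA methyltransferases Dnmt3a (log2 fold change −1.81) and Dnmt3b (−2.13) and the Nodal antagonist Lefty1 (−1.03). The list was lower by camera (adjusted p = 0.0321; adjusted p = 0.390 with an estimated correlation).

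Of 38 fibroblast genes, 14 rose and 0 fell, and 24 rose when adjusted over the list alone (camera adjusted p = 5.52e-12; adjusted p = 0.353 with an estimated correlation). Tagln, an actin-binding protein of contractile cells, rose from 21.4 to 144 ± 7.91 CPM, and Col1a2, a chain of type I collagen, from 141 to 510 ± 68.4. Acta2, smooth muscle actin, was counted once in the control and was higher by a ratio of 30.9 (95% interval 5.44 to 1230). Timp3, an inhibitor of matrix metalloproteinases, had a log2 fold change of 1.58 (SE 0.32). Together the list stood at 5246 CPM in the control, 10636 and 12362 in shTrim28, and 4893 and 5672 in the libraries labelled shWtx. Feeder cells had been depleted by replating before extraction, and 34 of the 38 genes had at least 3 counts in the control.

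Of 16 trophoblast genes, 5 rose and 0 fell, and 7 rose when adjusted over the list alone (camera adjusted p = 0.000352; adjusted p = 0.353 with an estimated correlation). They included Id2, an inhibitor of basic helix-loop-helix factors (log2 fold change 2.30, adjusted p = 0.00149), and the placental hormone gene Prl2c2 (1.28), whose reads could be shared with near-identical copies. The keratins of simple epithelia were also higher, Krt8 with a log2 fold change of 2.12 and Krt18 by a ratio of 11.8 (95% interval 3.17 to 99.0) over 2 counts in the control. In all, 6 of the 16 also stood on another list. Of 19 Wnt targets, 4 rose and 0 fell (6 rose adjusted over the list alone), namely Cd44, Id2, Ccnd2 and Tcf4, with log2 fold changes from 0.99 to 2.30 (camera adjusted p = 0.0150; adjusted p = 0.353 with an estimated correlation). Of 13 mesendoderm genes, 5 rose, among them Pdgfra (1.81), Hoxb1 (2.36) and Osr1 (2.15), and 1 fell, the ligand Bmp4 (−3.72). That list did not pass (camera adjusted p = 0.136). Trophoblast genes summed to 1630 CPM in the control, 3278 and 3725 in shTrim28, and 1830 and 2042 in the libraries labelled shWtx. Wnt targets summed to 1435, to 2293 and 2506, and to 1382 and 1453 in the same order. Like fibroblast genes, both were highest in shTrim28, and whether feeder cells gave part of these reads was not tested.

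Of 24 glycolysis genes, 8 fell and 0 rose, and 14 fell when adjusted over the list alone (camera adjusted p = 1.6e-11; adjusted p = 0.353 with an estimated correlation). The glucose transporters Slc2a3 (log2 fold change −1.34) and Slc2a1 (−1.30), Ldha (−1.14) and Pfkl (−1.28) had the lowest p. Of 39 genes of the Trim28 silencing machinery, 4 fell, which were Trim28 itself, Dnmt3a, Dnmt3b and Zfp57, a zinc finger protein of imprinted loci (−1.46). The list was lower by camera (adjusted p = 0.000594, and adjusted p = 0.358 with an estimated correlation). It holds the hairpin target, so part of that result was set by the design, and no test without Trim28 was run. Its median was −0.15, with 15 of 39 genes above 0. Of its genes 5 also stood on another list, among them Dnmt3a and Dnmt3b, named above for the primed epiblast. Of 34 imprinted genes, 3 rose and 2 fell, with Igf2 (2.51) and Mest (1.33) higher and Usp29 (−0.997) and Snrpn (−1.004) lower (camera adjusted p = 0.498). Of 16 genes of 2-cell-like cells, only Calcoco2 passed (−1.51), and Tcstv3 (0.88, adjusted p = 0.14) and Dub1 (1.04, adjusted p = 0.0865) did not (camera adjusted p = 0.91). Gm4981 was at 0 in the control and at least 2.44-fold higher, without passing the threshold (adjusted p = 0.0613).

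Among the other lists in shTrim28, 5 were lower by camera with few members past the threshold. They were cell cycle (2 of 37 fell, adjusted p = 9.52e-05), cholesterol synthesis (1 of 22, adjusted p = 0.000118), germline (1 of 8, adjusted p = 0.0227), ribosomal proteins (0 of 77, adjusted p = 1.32e-11) and oxidative phosphorylation (0 of 76, adjusted p = 0.000118). With an estimated correlation the first 3 had adjusted p = 0.353, ribosomal proteins adjusted p = 0.528 and oxidative phosphorylation adjusted p = 0.533. Ribosomal proteins had a median log2 fold change of −0.396 and oxidative phosphorylation −0.237. All genes over 400 CPM had a median of −0.292 and transcripts under 2000 bases −0.185, a shift that camera does not remove. Medians of the first 3 lists were −0.475, −0.636 and −0.54. The remaining lists did not pass. Of KRAB zinc finger genes 1 of 86 rose and 2 fell (adjusted p = 0.199), of endoderm 2 of 15 rose and 1 fell (adjusted p = 0.157), and of the interferon response 2 of 20 rose (adjusted p = 0.188). Of neuroectoderm 2 of 15 fell (adjusted p = 0.498, with a median of 0.51 and a lower direction in the test), of Nrf2 targets 2 of 24 rose and 1 fell (adjusted p = 0.498), and of p53 targets 3 of 28 rose and 1 fell (adjusted p = 0.166). No replication histone of 28 passed (adjusted p = 0.166). Of unfolded protein stress 1 of 29 rose and 2 fell (adjusted p = 0.119), and of the Wnt degradation complex 1 of 26 rose and 1 fell (adjusted p = 0.837, with a median of 0.23 and a lower direction in the test).

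Single genes with the largest changes came from low counts on the higher side. The 10 with the largest rise were at 0 in the control, which makes each fold a lower bound. They were Fam114a1 (at least 5.52-fold), Cthrc1, a secreted collagen repeat protein (5.25), Aspa (5.07), the complement protease C1r (4.34), Copz2 (4.34), Tada1l (4.07), Klhdc8a (3.8), Cyp2j13 (3.44), the translesion polymerase Rev1 (2.99) and Pnpla1 (2.35). The 10 with the largest fall were Nr0b1, Trim28, Ppp1r14a (log2 fold change −3.76), Bmp4, Tcf15 (−3.41), Rdm1 (−3.22), H2-T23 (−3.06), Zfp42, Pla2g1b (−2.83) and Slc25a33 (−2.76). In H2-T23, a class Ib histocompatibility gene, 13.4% of the transcript was sequence repeated in other genes, so its counts may hold reads of paralogs. Without shTrim28 replicate 1 edgeR called 0 genes (1675 at an unadjusted p under 0.05), here and in the comparison of the libraries labelled shWtx with the control, while the median log2 fold change of the pluripotency genes was −1.21. Without the library labelled shWtx replicate 1 it called 394, and with quantile normalization, the DESeq2 Wald test and no filter the counts were 308, 278 and 319.

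Of the repeats, 10 of 16 IAP elements, 28 of 87 LINE-1 elements and 3 of 5 satellites were higher in shTrim28 relative to gene reads, and none of these groups passed with an estimated correlation (adjusted p from 0.857 to 0.865). The median log2 fold change was 1.31 for LINE-1 elements and 1.16 for all repeats. IAPEz-int, the internal part of an endogenous retrovirus, rose from 285 to 2704 ± 389 CPM of gene reads (log2 fold change 3.25, SE 0.60, adjusted p = 7.75e-05). The major satellite GSAT_MM rose from 3486 to 17460 ± 2695 (2.32, adjusted p = 0.000204). Of 900 elements, 188 were higher and 1 was lower. Scaled to the repeats' own median, 19 were higher and 28 lower; scaled to their own total, 36 and 14; to DNA transposons, 8 and 42; and with quantile normalization, 24 and 11. Chemoreceptor genes were 6.92 and 4.54 times the control level in the same libraries.

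Of 16 IAP elements, 10 rose and 15 rose when adjusted over the group alone (camera adjusted p = 3.18e-05; adjusted p = 0.857 with an estimated correlation). IAPLTR1_Mm (log2 fold change 3.01, adjusted p = 0.000484) and IAPLTR1a_Mm (2.80) were among them. Of 9 MERVK10C and RLTR10 elements, 8 rose, with RLTR10 at 3.13, RLTR10-int at 2.36 and MMERVK10C-int at 2.35 (camera adjusted p = 0.000382; adjusted p = 0.857 with an estimated correlation). Of 87 LINE-1 elements, 28 rose, with L1_Mm at 2.61, L1Md_F at 2.58 and L1Md_F2 at 1.90 (camera adjusted p = 0.000316; adjusted p = 0.865 with an estimated correlation). Of 5 satellites, 3 rose, among them SYNREP_MM (3.08) and MurSAT1, which was at 0 in the control and at least 2.44-fold higher (camera adjusted p = 0.0467; adjusted p = 0.857 with an estimated correlation). Scaled to the repeats' own median, the calls were 1 IAP element, 2 of MERVK10C and RLTR10, 10 LINE-1 elements and 1 satellite, all higher. ORR1 and MT elements were higher by camera (13 of 45 rose, adjusted p = 0.000444; adjusted p = 0.865 with an estimated correlation).

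Of 7 MERVL and MT2 elements, MERVL-int passed (1.49, adjusted p = 0.0371), while MERVL_2A-int (1.37, adjusted p = 0.0581) and MT2A (1.12, adjusted p = 0.0985) did not (camera adjusted p = 0.734). MT2A changed sign to −0.05 when scaled to the repeats' own median and to −0.24 when scaled to DNA transposons. Of 27 SINEs, 0 passed, and the group lay below the other repeats by camera (adjusted p = 0.000118; adjusted p = 0.865 with an estimated correlation) with a median of 0.51, and with 8 of 26 lower when scaled to the repeats' own median. B2_Mm1a (−0.95, adjusted p = 0.0563), B2_Mm1t (−0.93, adjusted p = 0.0744) and B2_Mm2 (−0.77, adjusted p = 0.124) missed the threshold, as did LTR85b (−1.51, adjusted p = 0.0776). The small nucleolar RNA U17 was the 1 element that fell (−1.54, adjusted p = 0.0304). Structural RNA had 3 of 27 higher and 1 lower (median 0.57, with a lower direction in the test; camera adjusted p = 0.00127; adjusted p = 0.857 with an estimated correlation). The groups GLN and MuLV, MusD and ETn, VL30 and other ERVK did not pass, with adjusted p = 0.527, 0.734, 0.626 and 0.115. The 8 elements with the largest rise were at 0 in the control, from MER70A (at least 3.17-fold), MurSAT1, Charlie13b (1.99), LTR52-int (1.81), C573_MM (1.72), LTR80A (1.63) and Charlie4 (1.45) to LTR84a (1.36). Without the library labelled shWtx replicate 1, without replicate 2, or with only the 2 groups fitted, edgeR called 0 repeats (176, 192 and 148 at an unadjusted p under 0.05), and 437 without shTrim28 replicate 2.

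**Figure D2:**
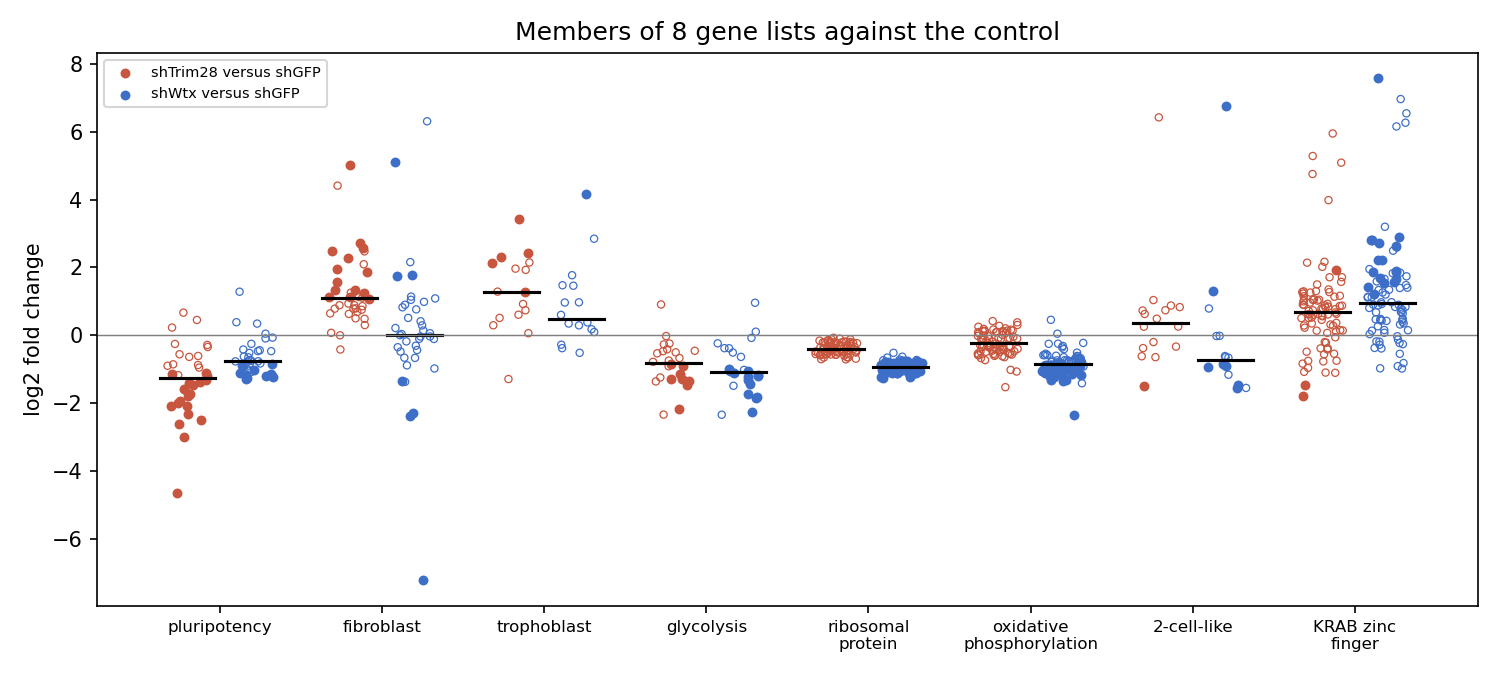
Log2 fold change of each tested member of selected gene lists in the comparisons. Filled points passed adjusted p 0.05, open points did not, and the black bar is the list's median. Pluripotency genes in shTrim28 have a median of −1.26, and ribosomal protein genes in the libraries labelled shWtx have a median of −0.94.

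The second comparison asked which genes differed in the libraries labelled shWtx, in which no lower level of Fam123b was detected. Of ribosomal protein genes 71 of 77 fell, and of oxidative phosphorylation genes 37 of 76, relative to the control, and as lists both had adjusted p = 0.528 with an estimated correlation. Rpl36, a protein of the large ribosomal subunit, went from 1597 to 668 ± 17.6 CPM (SD, n = 2), a log2 fold change of −1.26 (SE 0.27, adjusted p = 0.00181). Slc7a11, the cystine and glutamate antiporter, rose from 32.8 to 429 ± 17.5 (3.73, SE 0.42, adjusted p = 2.58e-07), and Eif2ak2 (PKR), a kinase activated by double-stranded RNA, rose from 46.6 to 411 ± 108 (3.16, SE 0.37, adjusted p = 6.12e-07). Of the 10878 genes, 1721 passed, 1184 higher and 537 lower, and with quantile normalization 558 were higher and 92 lower. Among genes with a transcript length 815 were higher and 631 lower, 589 and 325 with the background subtracted, and 299 and 156 without repeated sequence as well. The shift followed level and length: the median log2 fold change was 0.65 in genes under 25 CPM and −0.69 in those over 400, and −0.64 in transcripts under 2000 bases and 0.68 in those over 6000. The corresponding values in shTrim28 were 0.41 and −0.29, and −0.19 and 0.50.

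Of 77 ribosomal protein genes, 71 fell and 76 fell when adjusted over the list alone, with a median of −0.94 (camera adjusted p = 1.91e-31; adjusted p = 0.528 with an estimated correlation). Rps16 (−1.23), Rps9 (−1.12) and Rpl36a (−1.16) were among them. Ribosomal protein genes have many processed pseudogenes, and 31.9% of the Rpl36 transcript was sequence repeated in other genes. The list took 16.9% of gene counts in the control, 11.9% and 14.4% in shTrim28, and 8.30% and 9.53% in the libraries labelled shWtx, while chemoreceptor genes stood at 13.3 and 11.5 times the control in the latter. The number that fell was 9 with quantile normalization, 2 with no filter, 35 at a mean count of 20, and 0 without the library labelled shWtx replicate 1. Of 76 genes of oxidative phosphorylation, 37 fell, and 49 when adjusted over the list alone, with a median of −0.85 (camera adjusted p = 1.27e-16; adjusted p = 0.528 with an estimated correlation). They included Uqcr (−1.32), Ndufa2 (−1.34), Atp5o (−1.31) and Atp5e (−1.22), which belong to complexes III, I and V.

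Of 24 glycolysis genes, 13 fell, and 14 when adjusted over the list alone (camera adjusted p = 1.08e-09; adjusted p = 0.528 with an estimated correlation), with Slc2a1 (−1.72), Ldha (−1.43), Pfkl (−1.82) and Eno1 (−1.33) leading. Of 34 pluripotency genes, 10 fell and 0 rose, and 13 when adjusted over the list alone (camera adjusted p = 6.51e-07; adjusted p = 0.528 with an estimated correlation). Tdgf1 (Cripto), a Nodal coreceptor (−1.30), Dppa5a (−1.19), Klf2 (−1.26) and Zfp42 (−1.01) were among them. Pou5f1 (−0.73, adjusted p = 0.0572), Sox2 (−0.84, adjusted p = 0.0586) and Nanog (−0.47, adjusted p = 0.299) missed the threshold. Of 86 KRAB zinc finger genes, 17 rose and 0 fell, and 18 when adjusted over the list alone (camera adjusted p = 0.00195; adjusted p = 0.532 with an estimated correlation). The list's median was 0.95, beside 0.65 for all genes under 25 CPM. Its 139 members, tested or not, summed to 2867 CPM in the control. Zfp473 (2.63), Zfp37 (2.71), Zfp874 (2.23) and Zfp641, at 0 in the control and at least 6.17-fold higher, had the lowest p.

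Of 16 genes of 2-cell-like cells, 2 rose and 5 fell (camera adjusted p = 0.0219; adjusted p = 0.528 with an estimated correlation). Tcstv3 (−1.47) and Zscan4c (−0.91) were lower, and Dub1 (1.31) and Gm4981, at 0 in the control and at least 3.43-fold higher, were higher. Both Zscan4c and Dub1 have close paralogs whose reads may be shared. Of 20 interferon response genes, 4 rose and 3 fell (camera adjusted p = 0.872). Besides Eif2ak2, those higher included Oas3 by a ratio of 11.8 (95% interval 3.88 to 58.7) and Oasl1 by 13.9 (3.66 to 117), and Ifitm3 was lower (−1.27). Of 24 Nrf2 targets, 2 rose and 4 fell (camera adjusted p = 0.134), with Gsta4 (−1.13), Tkt (−1.07) and Fth1 (−0.91) lower. Of 38 fibroblast genes, 3 rose and 4 fell (camera adjusted p = 0.605, with a median of 0.02 and a lower direction in the test). Acta2 was higher by a ratio of 37.5 (6.53 to 1500) and Tagln by 1.75 on the log2 scale, whereas Ccl2 (−2.29) and Loxl1, a lysyl oxidase, were lower. Loxl1 had 14 counts in the control and 0 in both libraries, at least 9.08-fold lower.

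Of 19 Wnt targets 1 rose (camera adjusted p = 0.81), and of 26 genes of the Wnt degradation complex 0 passed (camera adjusted p = 0.486). The 10 genes with the largest rise were at 0 in the control. They were Ermn (at least 9.59-fold), Aspa (9.59), Pnpla1 (8.91), Cyp2j13 (8.57), Btbd16 (8.22), Nrk (8.05), 9530053A07Rik (7.19), Nyx (6.85), Phex (6.34) and Gm906 (6.34). The largest falls after Loxl1 were in Tgfbi (−2.60), Mgp (−2.59), Nle1 (−2.49), Gpc3 (−2.44), Crabp1 (−2.38), Mmp3 (−2.37), Cox6b2 (−2.36), Gas1 (−2.32) and Ccl2. Tgfbi, Mgp, Gpc3 and Mmp3 encode proteins of the extracellular matrix and cell surface or enzymes that cut it, and Gas1 a membrane protein of the Hedgehog pathway. Without shTrim28 replicate 1 edgeR called 0 genes in this comparison too (2804 at an unadjusted p under 0.05), and without the libraries labelled shWtx replicates 1 and 2 it called 469 and 1282. The DESeq2 Wald test called 548, no filter 1143 and a mean count of 20 848.

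Most repeats were higher in the libraries labelled shWtx relative to gene reads, with a median log2 fold change of 2.21 over all elements. GSAT_MM rose from 3486 to 52160 ± 12690 CPM of gene reads (3.90, SE 0.51, adjusted p = 3.64e-11), and IAPEz-int from 285 to 5611 ± 1465 (4.30, adjusted p = 7.68e-09). Of 900 elements, 740 were higher and 3 lower. Scaled to their own total, 444 were higher and 39 lower. Scaled to the repeats' own median, 47 were higher and 116 lower; to DNA transposons, 29 and 165; and with quantile normalization, 73 and 54.

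Of 16 IAP elements, 15 rose (camera adjusted p = 0.00211; adjusted p = 0.863 with an estimated correlation), with IAPLTR3-int at 4.08 and IAPLTR3 higher by a ratio of 36.5 (6.34 to 1460). Of 87 LINE-1 elements, 84 rose, with L1Md_F at 3.83, L1_Mm at 3.69 and L1Md_F2 at 2.81 (camera adjusted p = 0.000257; adjusted p = 0.863 with an estimated correlation). Of 5 satellites, 3 rose, including SYNREP_MM (4.25) and MurSAT1 (at least 4.63-fold; camera adjusted p = 0.159). Scaled to the repeats' own median, 4 IAP elements, 11 LINE-1 elements and 2 satellites were higher, and 1 LINE-1 element and 1 satellite lower. Of 27 SINEs, 21 rose, and scaled to the repeats' own median 0 of 26 were higher and 15 lower. B4 (1.70), B1_Mur1 (1.80) and ID_B1 (1.61) rose on gene scaling and went to −0.47, −0.36 and −0.55 on the repeats' own median. Of 7 MERVL and MT2 elements, 3 rose, MT2A (2.03), MERVL_2A-int (1.84) and MERVL-int (1.27), and on the repeats' own median 0 were higher and 4 lower. The camera test placed SINEs and MERVL elements below the other repeats, each with adjusted p = 0.0329 (adjusted p = 0.863 with an estimated correlation).

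MERVK10C and RLTR10 (9 of 9 rose), ORR1 and MT (43 of 45) and other ERVK (94 rose and 7 did not pass) were higher by camera, with adjusted p = 0.03, 0.000514 and 0.0282 (adjusted p = 0.863 with an estimated correlation). GLN and MuLV (24 of 28), MusD and ETn (4 of 5) and VL30 (2 of 3) did not pass, with adjusted p = 0.296, 0.735 and 0.715. Structural RNA lay below the other repeats (5 of 27 rose, 1 fell; camera adjusted p = 6.78e-17; adjusted p = 0.228 with an estimated correlation). The 3 elements that fell were (CGGAG)n (−1.92), the Y RNA HY3 (−1.39) and U17 (−1.39), and (CGGG)n (−0.99, adjusted p = 0.0537) and 7SLRNA (−0.80, adjusted p = 0.074) missed the threshold. The 8 largest rises were again from 0 counts, MER70A (at least 8.22-fold), MER113A (5.48), Charlie4 (5.14), Charlie13b (4.63), MurSAT1 (4.63), LTR84a (3.94), LTR69 (3.77) and Charlie23a (3.60). Without the library labelled shWtx replicate 1 the call was 353 repeats, all higher.

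**Figure D3:**
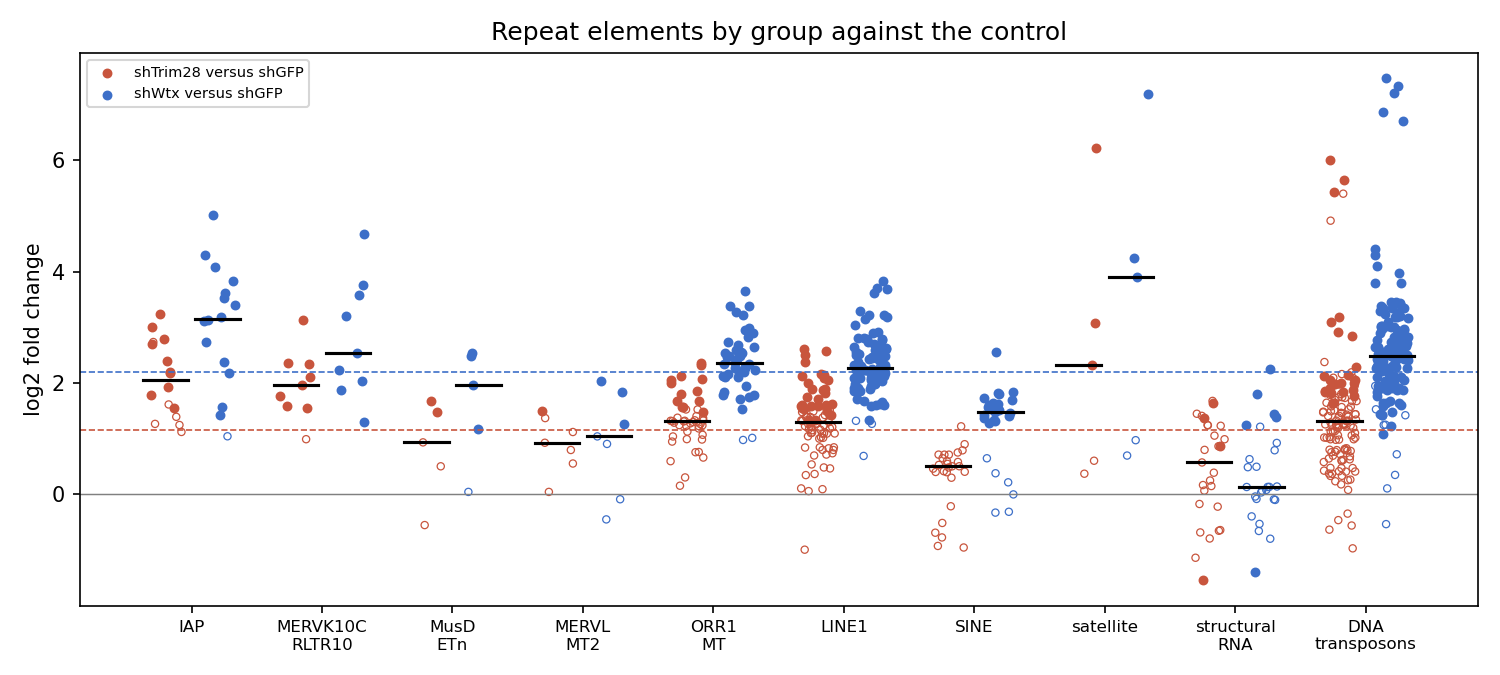
Log2 fold change of each tested element of the repeat groups relative to gene reads. Filled points passed adjusted p 0.05, open points did not, black bars are group medians and dashed lines the median of all repeats, at 1.16 for shTrim28 and 2.21 for the libraries labelled shWtx against the control.

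The third comparison set shTrim28 against the libraries labelled shWtx, without the control in the difference. Of fibroblast genes 24 of 38, of trophoblast genes 6 of 16 and of imprinted genes 10 of 34 were higher in shTrim28, and 13 of 34 pluripotency genes were lower. With an estimated correlation none of these lists passed (adjusted p from 0.488 to 0.527). Gas1 stood at 168 ± 73.7 CPM in shTrim28 and at 15.3 ± 5.46 in the libraries labelled shWtx (log2 fold change 3.45, SE 0.38, adjusted p = 2.66e-06). Mrgpre, an orphan receptor of sensory neurons, stood at 47.2 ± 23.8 and 684 ± 18.2 (−4.13, SE 0.30, adjusted p = 1.63e-09). In all, 593 genes were higher and 1069 lower in shTrim28.

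Of 38 fibroblast genes, 24 were higher and 0 lower, and 27 higher when adjusted over the list alone (camera adjusted p = 4.9e-17; adjusted p = 0.488 with an estimated correlation). They included Dcn (2.12), S100a4 (1.73), Col1a2 (1.45) and Loxl1, at 0 in the libraries labelled shWtx and at least 13.2-fold higher. Of 34 pluripotency genes, 13 were lower and 1 higher, and 14 and 1 when adjusted over the list alone (camera adjusted p = 4.47e-05; adjusted p = 0.488 with an estimated correlation), led by Zfp42 (−1.97), Nr0b1 (−3.64), Utf1 (−1.46) and Fbxo15 (−1.32). Of 34 imprinted genes, 10 were higher and 1 lower, the same numbers as when adjusted over the list alone (camera adjusted p = 0.00188; adjusted p = 0.527 with an estimated correlation), including Mest (2.16), Dlk1 (1.71), Dcn and Gnas (1.011). Of 16 genes of 2-cell-like cells, 5 were higher and 1 lower, and 6 and 1 when adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.488 with an estimated correlation), with Tcstv3 (2.35), Tcstv1 (1.99), B020004J07Rik (1.40) and Tmem92 (1.54) higher. Summed, both of these lists were highest in the control. Imprinted genes stood at 8352 CPM there, 7522 and 7518 in shTrim28, and 5958 and 6415 in the libraries labelled shWtx. Genes of 2-cell-like cells stood at 3293.5, at 2678 and 3083, and at 2200 and 1945 in the same order. Of 16 trophoblast genes, 6 were higher and 1 lower (camera adjusted p = 0.0128; adjusted p = 0.527 with an estimated correlation), with Id2 (2.13), Krt8 (2.63), Krt18 (2.84) and Prl2c2 (0.98) higher. Of 20 interferon response genes, 7 were higher and 5 lower (camera adjusted p = 0.392), with B2m (1.44) and Ifitm3 (1.32) higher and Eif2ak2 (−1.37) and Oas3 (−2.18) lower.

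Of 19 Wnt targets, 6 were higher and 1 lower in shTrim28 (camera adjusted p = 0.0322; adjusted p = 0.527 with an estimated correlation). Ribosomal proteins (20 of 77, camera adjusted p = 5.28e-17) and oxidative phosphorylation (26 of 76, camera adjusted p = 2.58e-12) were also higher in shTrim28, each with adjusted p = 0.527 with an estimated correlation. Their median log2 fold changes were 0.57 and 0.67. In the same comparison all genes over 400 CPM had a median of 0.43, and transcripts under 2000 bases 0.45. Both lists summed lower in every hairpin library than in the control. The other symbols with the largest differences were Crabp1 (3.83), Cthrc1 by a ratio of 15.3 (4.05 to 129) and Plcd1 by 6.34 (2.00 to 32.2) on the higher side. On the lower side they were Hrk by a ratio of 0.0587 (0.0114 to 0.191), Lrit1 by 0.0528 (0.00598 to 0.217) and Xrcc3 (−3.73). Without shTrim28 replicate 1 edgeR called 0 genes (3113 at an unadjusted p under 0.05), without replicate 2 it called 452, and without the libraries labelled shWtx replicates 1 and 2 it called 204 and 1100. The DESeq2 Wald test called 400, quantile normalization 730, no filter 912 and a mean count of 20 1037.

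Among repeats, 12 were higher and 594 lower in shTrim28, with a median log2 fold change of −1.05. Scaled to their own total, 29 were higher and 268 lower. Scaled to the repeats' own median, 7 were higher and 0 lower (edgeR); to DNA transposons, 38 and 0; and with quantile normalization in limma, 6 and 0. MT2_Mm, the LTR of MERVL, was higher in shTrim28 at 24370 ± 2911 against 10270 ± 823 CPM of gene reads (1.25, SE 0.36, adjusted p = 0.00873), and also under each of those scalings, with log2 fold changes of 1.53 on the own total and from 2.30 to 2.39 on the others. MT2A (−0.91, adjusted p = 0.0491) and MT2B2 (−0.86, adjusted p = 0.074) changed sign to 0.09 and 0.18 on the repeats' own median. The MERVL and MT2 group, with 1 of 7 higher and 1 lower, lay above the other repeats by camera (adjusted p = 7.86e-06; adjusted p = 0.787 with an estimated correlation), although its median was −0.11. Of 27 structural RNAs, 6 were higher and 1 lower, with U4 (1.30), U1 (1.21) and LSU-rRNA_Hsa (0.74) higher (median −0.01, with a higher direction in the test; camera adjusted p = 1.76e-27; adjusted p = 0.171 with an estimated correlation).

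Of 16 IAP elements, 11 were lower and 1 was higher in shTrim28 (median −1.28, with a higher direction in the test, which sets them against the other repeats; camera adjusted p = 0.956). The one higher was IAPLTR1_Mm, at 856 and 2108 CPM of gene reads in shTrim28 against 406 and 355 (1.97, SE 0.45, adjusted p = 0.00196), while IAPLTR3 (−2.27) and IAPLTR4 (−1.65) were lower. On the repeats' own median 0 IAP elements were higher and 0 lower. These are calls only, and this scaling moved the median log2 fold change of all repeats from −1.05 to −0.003. The lost call of IAPLTR1_Mm therefore does not show a smaller rise. Of 5 satellites, GSAT_MM (−1.58, adjusted p = 0.00116) and SYNREP_MM (−1.17, adjusted p = 0.0204) were lower, and MurSAT1 (−0.98, adjusted p = 0.0589) missed the threshold and went to 0.28 on the repeats' own median (camera adjusted p = 0.945). Leaving out shTrim28 replicate 2 or the libraries labelled shWtx replicates 1 or 2 left 1, 0 and 13 calls by edgeR (287, 88 and 275 at an unadjusted p under 0.05).

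**Figure D4:**
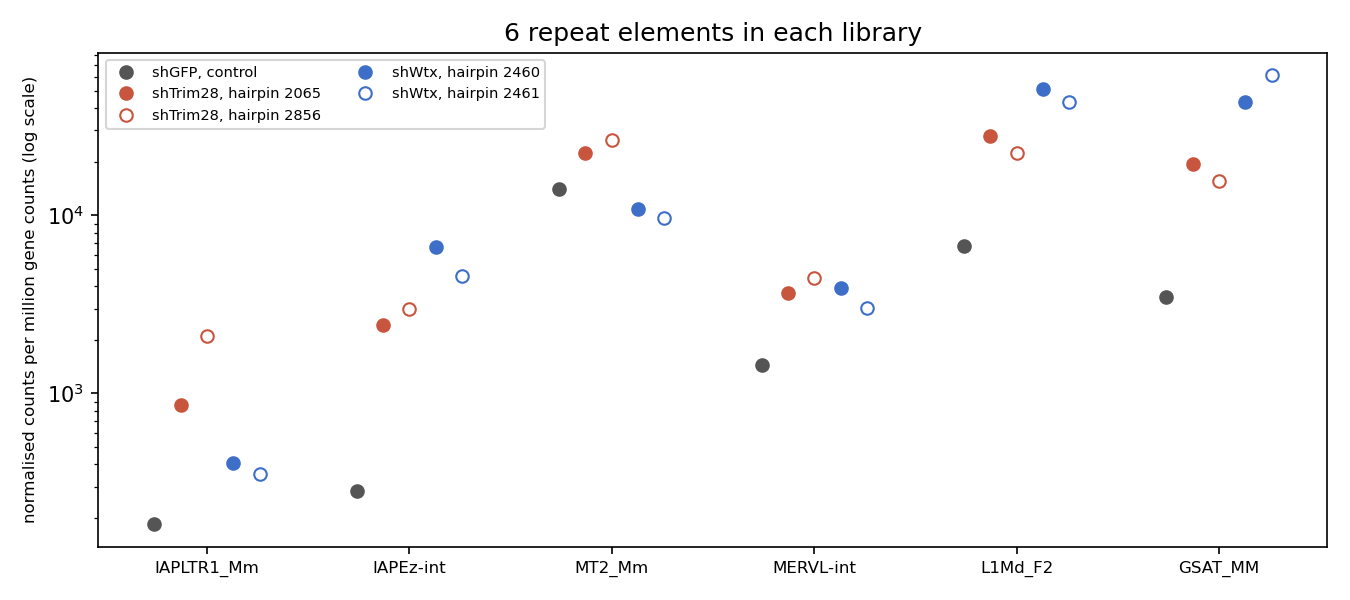
CPM of gene reads of 6 named repeat elements in each of the 5 libraries, on a log axis. GSAT_MM and IAPEz-int are highest in the libraries labelled shWtx, and IAPLTR1_Mm and MT2_Mm are highest in the shTrim28 libraries.

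The changes of shTrim28 and of the libraries labelled shWtx against the control were compared with each other. Across genes, which are not independent replicates, their log2 fold changes correlated at r = 0.834, where unchanged groups simulated against the same control gave 0.729. Their covariance was 1.68, against 0.320 simulated. Both rose in 317 genes and both fell in 91, and how many would be shared through the common control was not determined. For repeats r was 0.903 (0.715 simulated), the covariance 1.09 (0.266 simulated), and 184 were higher in both. The control was 1 library and could not be split, so part of these correlations may come from it. The hairpins of a target correlated at r = 0.713 for shTrim28 and 0.871 for the libraries labelled shWtx when each was set against that control, but shTrim28 replicate 1 correlated as closely with the library labelled shWtx replicate 1 (0.716). For repeats the shTrim28 hairpins correlated at 0.706, and libraries of different targets at 0.757 to 0.799. After centring genes on the mean of the 5 libraries, r was −0.04 within shTrim28, 0.44 within the libraries labelled shWtx and −0.51 to −0.23 between targets, and no values for unchanged libraries were simulated for these.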

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

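The tests on background reads and repeats inside transcripts, the comparison of single repeats with the libraries labelled shWtx, and the subtraction of a background were chosen only after the results were seen. The prediction for the X chromosome was written before its result.

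Counts appeared in genes that the comparisons hardly used. The 1349 chemoreceptor genes, of which 15 were tested, stood at 6.92 and 4.54 times the level of the control in shTrim28 replicates 1 and 2, and at 13.32 and 11.46 times in the libraries labelled shWtx replicates 1 and 2. Ly6a (Sca-1), a surface antigen, was the 1 gene that passed in opposite directions in both comparisons with the control and also passed between the targets. It was singled out after its values were seen. Its level was 62.4 CPM in the control, 116 and 175 in shTrim28, and 26.2 and 17.3 in the libraries labelled shWtx. The log2 fold changes were 1.29 (adjusted p = 0.0319 in edgeR) and −1.46 (adjusted p = 0.0245), and the difference was 2.747 (adjusted p = 1.29e-05). Passing in that difference was part of the selection, so its p-value adds no separate support. Without shTrim28 replicate 1 edgeR called 0 genes in any of these comparisons (1675, 2804 and 3113 at an unadjusted p under 0.05).

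Summed reads of DNA transposons, LINEs and LTR elements were higher in all 4 hairpin libraries than in the control, in the order of the chemoreceptor counts, while those of SINEs were lower in both shTrim28 libraries and those of ribosomal and small nuclear RNA were highest in shTrim28. A candidate explanation is a background of reads in proportion to sequence length: on a line over the chemoreceptor level, drawn through the control and the mean of the libraries labelled shWtx, the median log2 of observed over predicted was −0.04 and −0.203 in shTrim28 replicates 1 and 2 (DNA transposons, LINEs and LTR elements between −0.27 and 0.08), but ribosomal RNA (0.63 and 0.538), small nuclear RNA (0.622 and 0.434) and SINEs (−0.167 and −0.519) lay off it, and 16 elements were above and 23 below by over 0.5 in both. Genomic DNA as its source stayed open, because the ratio of X-linked to autosomal reads per kilobase in genes at 0 in the control was 0.615 (95% bootstrap interval 0.521 to 0.719) in the library labelled shWtx replicate 1 and 0.701 (0.550 to 0.874) in replicate 2, whose interval includes 0.8, and 0.774 (0.572 to 1.0) and 0.786 (0.629 to 0.965) in shTrim28. For the IAP group, known targets of Trim28 silencing, and the MERVL and MT2 group as wholes the background cannot be told apart from an effect of Trim28, because members went both ways around medians of −0.04 (−0.245 and 0.189 in replicates 1 and 2) and 0.528 (0.296 and 0.739, permutation p = 0.00045) relative to DNA transposons (permutation p across elements, not hairpins), and the hairpins also disagreed for MERVK10C and RLTR10 (medians −0.09 and 0.461 on the line; 0.357 relative to DNA transposons, permutation p = 0.00025) and LINE-1 (0.111 and −0.267; 0.064, permutation p = 0.015). For IAPLTR1_Mm and MT2_Mm the background as the whole cause was argued against, because both shTrim28 libraries lay above both libraries labelled shWtx, which held more background (log2 fold change 1.969, adjusted p = 0.00196, and 1.247, adjusted p = 0.00873 in edgeR). Both were picked by this same call, as the only members called higher of 16 IAP and 7 MERVL and MT2 elements. The call is adjusted over all 900 elements, but has no separate test behind it. Leaving out a library ended either call, at log2 fold changes of at least 1.12. MT2_Mm did not pass against the control (adjusted p = 0.151 in shTrim28). For it a lower level in the libraries labelled shWtx stays open beside an effect of Trim28. Of the 16 elements above the line by over 0.5 in both, 1 was an IAP element, 2 were of the MERVL and MT2 group and 9 were structural RNA.

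Symbol-named genes called higher in both comparisons with the control held more repeated sequence than others. The median percent of their 24-base words found in at least 10 genes was 0.52 in 194 called genes (97.9% with a value), against 0.0 in the other tested genes (permutation p = 0.0001, the smallest that 10000 permutations can give). Reads of repeats inside transcripts may therefore account for part of these calls, and the test does not say for which genes. The called genes were also longer, with a median of 4310 bases against 3584, and the permutation did not match length. A background in proportion to length is thus not told apart from such reads. At least 1% of repeated sequence was found in 42.1% of the called genes, against 20.2% of others. In genes called lower it was 26.9% against 20.4% in shTrim28, and 23.1% against 20.5% in the libraries labelled shWtx. With a length-proportional background subtracted and transcripts with at least 1% of repeated sequence left out, 387 genes passed in shTrim28 and 455 in the libraries labelled shWtx. No separate biological explanation was tested for this pattern.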

How the results depend on the processing

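Background subtraction, the limit on repeated sequence, transcripts with a length only, the worth of 1 read and scaling to DNA transposons were tried only after the results were seen. Among the 139 named genes that passed, 929 of the values under the alternatives fixed beforehand stayed past the threshold in the same direction, 357 missed it and 0 reversed. Among the 56 named repeats that passed, 424 stayed, 169 missed it and 12 reversed. No paired analysis was possible because the libraries of a target differ by hairpin, carry no replicate number in the labels and have a single control. The pseudocount alternative was not run, since the values are counts. Small changes were mostly missed in simulation, and how much of that comes from depth, the single control or the spread was not tested. With 200 simulated changed genes, a 2-fold change was recovered for 4% of them in shTrim28 and 9% in the libraries labelled shWtx.

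For shTrim28 against the control, 710 genes passed, and 308 with quantile normalization, 278 with the DESeq2 Wald test, 319 with no filter, 387 with background and repeated sequence removed, and 0 to 798 when 1 hairpin library was left out. For the libraries labelled shWtx the main count was 1721, and the others were 650, 548, 1143, 455 and 0 to 2340, with 848 at a mean count of 20 and 914 with the background subtracted. For shTrim28 against the libraries labelled shWtx 1662 passed, and 730, 400, 912, 676 and 0 to 1100 under the same alternatives, with 1037 at a mean count of 20. The 0 arose in each case without shTrim28 replicate 1 in edgeR (1675, 2804 and 3113 at an unadjusted p under 0.05). Fewer genes than the 10878 of the main fit enter at a mean count of 20, and more without a filter. The DESeq2 Wald test covered 2021, 6660 and 4340 genes in the comparisons in that order. With the background subtracted 9608 were tested, and 7629 without repeated sequence as well. Leaving out a library gave 9368 to 11251. These counts are therefore not of the same genes, and how much of each difference comes from that was not tested. For quantile normalization the cause was not tested.

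For repeats in shTrim28, 189 passed, and 84 with DESeq2 size factors, 35 with quantile normalization, 0 with only the 2 groups fitted (148 at an unadjusted p under 0.05), 50 scaled to their own total, 47 to their own median, 50 to DNA transposons, and 0 to 437 with a hairpin library left out. In the libraries labelled shWtx 743 passed, and 127, 483, 163 and 194 with quantile normalization, own total, own median and DNA transposons, and 353 to 782 with a library left out. Between the targets 606 passed, and 6, 297, 7 and 38 under the same scalings, 333 with the DESeq2 Wald test, and 0 to 800 with a library left out. Quantile normalization and scaling to the own median remove a shift common to all repeats by construction, and scaling to DNA transposons one that those share. On the own total 36 were higher and 14 lower in shTrim28, 444 and 39 in the libraries labelled shWtx, and 29 and 268 between the targets. The number of repeats tested also differed from the 900 of the main fit. It was 807 on the own total, 855 on the own median and 857 on DNA transposons. Between the targets the DESeq2 Wald test covered 673, and in shTrim28 the fit of only the 2 groups covered 785. How much of each difference comes from that was not tested, and for the other alternatives the cause was not tested.

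Some repeats reversed under a scaling. In shTrim28 MT2A went from 1.12 to −0.045 on the own median and −0.237 on DNA transposons. In the libraries labelled shWtx, with quantile normalization, own median and DNA transposons in that order, B4 was −0.068, −0.473 and −0.727, B1_Mur1 −0.07, −0.364 and −0.619, MERVL_2A-int −0.059, −0.32 and −0.578, and MERVL-int −0.556, −0.905 and −1.162. ID_B1 was −0.552 and −0.81 and MT2A −0.138 and −0.394 under the latter 2. Between the targets MT2A was 0.06, 0.092 and 0.157, MT2B2 0.021, 0.177 and 0.244, and MurSAT1 0.285 and 0.374 under the latter 2. Fam123b, not called, went from 0.27 to −0.362 between the targets without shTrim28 replicate 2 and to 0.65 without the library labelled shWtx replicate 1; the cause was not tested.

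Of the gene lists 12 passed by camera in each comparison, and 0 with an estimated correlation and 0 by fry for 1 direction in each. By fry for either direction the numbers were 17, 16 and 0 for shTrim28, the libraries labelled shWtx and their difference. Of the repeat groups 7, 8 and 2 passed, 0 with an estimated correlation in each, 0, 1 and 1 by fry for 1 direction, and 2, 9 and 1 for either direction. The correlation of the changes of both targets was 0.7893 for genes at a mean count of 20 in place of 0.8335.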

Other observations

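Of the tests here, those on the fall of pluripotency genes were chosen only after the result was seen. Mrgpre, Slc7a11 and Eif2ak2 were the subject of a closer look after their values were seen. Mrgpre, a receptor of sensory neurons, stood at 9.72 CPM in the control, at 64.1 and 30.4 in shTrim28 and at 697 and 672 in the libraries labelled shWtx, with a log2 fold change of 6.23 (SE 0.51, adjusted p = 1.24e-09 in edgeR) in the latter. Slc7a11, the cystine and glutamate antiporter, also rose in shTrim28 (log2 fold change 2.43, adjusted p = 0.00049), by less than in the libraries labelled shWtx (difference −1.30, adjusted p = 0.00118). Eif2ak2, the kinase activated by double-stranded RNA, rose in shTrim28 by 1.785 on the log2 scale (adjusted p = 0.0038; difference −1.37, adjusted p = 0.000417). The share of repeated 24-base words in their transcripts was 3.45%, 3.46% and 3.40%.

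Several gene lists moved that the comparisons did not dwell on. In the libraries labelled shWtx, 7 of 37 cell cycle genes fell and 1 rose (camera adjusted p = 0.000613), 4 of 22 cholesterol synthesis genes fell (adjusted p = 0.000603) and 6 of 39 genes of the Trim28 silencing machinery fell (adjusted p = 0.00248). Lower by camera were also primed epiblast (4 of 13 fell, adjusted p = 0.0393), replication histones (2 of 28, adjusted p = 0.0371) and unfolded protein stress (2 of 29, adjusted p = 0.0371). All 6 had adjusted p = 0.528 with an estimated correlation. Between the targets, 17 of 86 KRAB zinc finger genes were lower in shTrim28 (adjusted p = 0.00362; adjusted p = 0.545 with an estimated correlation), 5 of 24 Nrf2 targets were higher and 2 lower (adjusted p = 0.00489), 4 of 15 endoderm genes were higher (adjusted p = 0.0310) and 1 of 8 germline genes was lower (adjusted p = 0.0352), the latter 3 with adjusted p = 0.527 with an estimated correlation. KRAB zinc finger genes had a median of −0.51 there, beside −0.32 for all genes under 25 CPM.

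Pluripotency genes fell in shTrim28, with a median log2 fold change of −1.26 in 34 genes. Dilution of transcripts by background reads was argued against, because the median differed by −1.25 from that of genes of the same level, and 0 of 10000 level-matched lists reached it (lowest −0.51). With a larger share of feeder cells as the whole cause, genes absent from fibroblasts would fall by 1 common factor. The fold changes differed by more than their approximate standard errors (Cochran's Q of 231.3 over 34 genes with 33 degrees of freedom, chi-square p = 1.3e-31). This cannot decide the question, because absence of these genes from fibroblasts was not measured. Fold changes in shTrim28 also varied with transcript length (median −0.19 under 2000 bases, 0.50 over 6000). The rise of fibroblast genes itself, from 5246 CPM to 10636 and 12362, stays open as feeder cells left after replating or as a change of the cells, and so does a contribution of either to the fall. An unusual control library as the whole cause was argued against, because shTrim28 also lay below the libraries labelled shWtx (28 of 34 genes, median −0.78 from level-matched genes, 0 of 10000 lists as low), though camera with an estimated correlation gave adjusted p = 0.488 for that difference, and a part shared with the libraries labelled shWtx stays open with an effect of Trim28.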
